A study of Rattus norvegicus with 12 samples.

How the data were processed

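Expression was measured on a single-colour Affymetrix rat array, 1 array per sample, in 12 samples of ventral midbrain cultures. Per the labels' protocols, cells from rat embryos at day 12 were grown for 6 days with basic fibroblast growth factor (20 ng/ml) and Sonic hedgehog (50 ng/ml) and for 3 more days without them. On day 9 they were depolarized with 56 mM KCl for 2 h or kept in control medium, and RNA was taken after a further interval of either 30 min or 2 h. Embryos of 4 pregnant rats were mixed into 3 groups that were treated separately, and RNA of duplicate cultures was pooled before hybridization. The 4 groups (control and depolarized at each collection time) held 3 arrays each, with replicate numbers 1 to 3 at 30 min and 4 to 6 at 2 h. The labels do not say whether the cultures of both collection times came from the same preparation.

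The deposited values are log2 expression summaries per probe set, made by the authors with RMA per the submitters' processing notes, which give no version. The log2 scale was taken from the values themselves, which lay between 4.41 and 14.58 with array medians from 8.33 to 8.43. Which arrays were normalized together is not stated. The table held 15923 probe sets, of which 57 array controls were left out and 15866 tested. The array's annotation, which can be old, gave 1 gene symbol for 12783 probe sets, several for 312 and none for 2771. No gene is named from a probe set with several symbols, and 0 symbols needed an update through the gene identifier in a current rat annotation. Array values carry no read depth, so the number of arrays limits the precision, and the table holds no detection calls.

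Differences were tested with limma 3.58.1 in R 4.3.3. A means model of the 4 groups was fitted to all 12 arrays (8 residual degrees of freedom) with empirical Bayes moderation, no replicate block and no further normalization. All p-values are two-sided, with Benjamini-Hochberg adjustment over all 15866 probe sets and a threshold of 0.05. Comparisons were depolarized against control at 30 min, depolarized against control at 2 h, the difference between these responses (interaction), and the controls collected at 2 h against those collected at 30 min. Differences are in log2 units with the standard error (SE) of the fit, and group levels are means with the SD of 3 arrays. As embryos were mixed and RNA was pooled, the SE, SD and p-values reflect spread between pooled cultures, not between animals.

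The 20 gene lists and 10 cell type marker lists, the designs, the naming rule and most alternatives were fixed before the data were examined. Of 781 list symbols, 627 were measured. Each gene of a list was taken at its probe set with the highest mean over all arrays. Lists of at least 5 measured genes were tested with limma's camera (preset correlation 0.01), adjusted over 30 lists and both collection times together, with an estimated correlation and with fry beside it. The list tests of the control difference and of the response difference were added after the data were seen, each adjusted over 30 lists. Member counts are given over all probe sets tested and adjusted over the list alone.

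Genes were named by rule. For each treatment comparison these were the 12 largest rises and 12 largest falls among genes with 1 symbol, past the threshold and with no overlap between the 3 depolarized and 3 control arrays, at the probe set with the lowest p. To these were added up to 4 members per list with the smallest p, at least Fos, Arc, Egr1, Nr4a1, Nr4a2, Bdnf, Homer1, Th, Slc6a3, Slc18a2, Ddc and Gfap, 6 genes each way for the response difference and 4 each way for the controls. Other members named as examples were chosen after their values were seen.

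Alternatives were fits of only the arrays compared, median centring, quantile normalization, leaving out the dimmest 25% or 50% of probe sets, array weights, a trended and robust prior, an ordinary equal-variance test, stricter thresholds, the replicate number as a block, and each array left out in turn. A loess correction of each array's trend on mean level, and the controls of the other collection time, were chosen after seeing the data. The fit was tested on simulated arrays with 50 probe sets changed at each size. At 30 min it recovered 22% of those changed by 0.25, 94% of those changed by 0.5 and 100% of those changed by 1 log2 unit, with 7 false calls. At 2 h the shares were 28%, 98% and 100%, with 7 false calls, and for the response difference they were 10%, 72% and 100%, with 8 false calls. The simulated arrays had independent noise and few changed probe sets, so these shares and false calls need not carry over to the real arrays.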

Results

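Gene expression was measured in rat ventral midbrain cultures after 2 h of depolarization with 56 mM KCl or of control medium. Cultures were collected 30 min or 2 h later, with 3 arrays in each of 4 groups. The design asks which transcripts depolarization changed at each collection time. Arrays of a group correlated at 0.9957 to 0.9979 across probe sets and arrays of different groups at 0.9717 to 0.9922. The first principal component, with 51.2% of the variance, separated the collection times, and the second component, with 24.5%, separated depolarized from control arrays. Array medians lay between 8.33 and 8.43 log2 units.

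**Figure D1:**
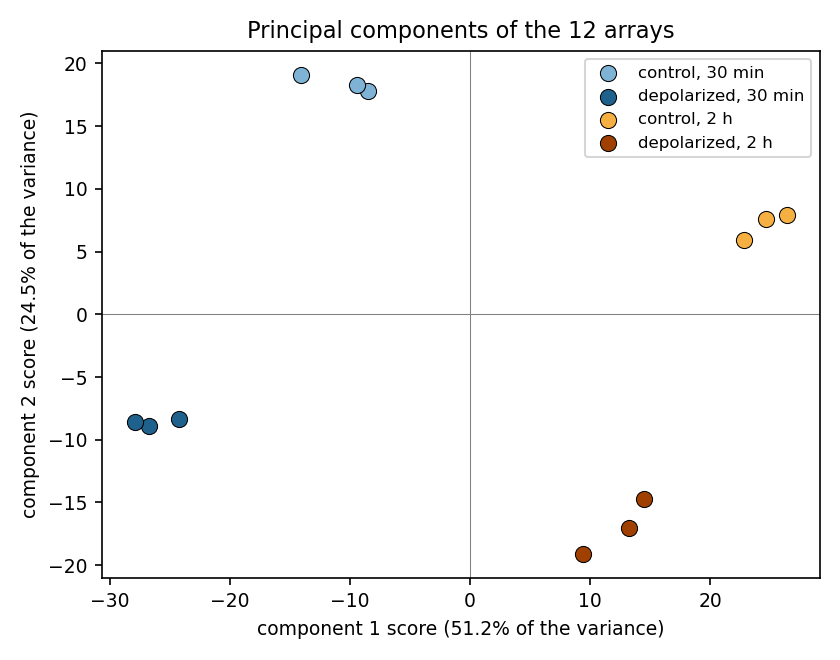
Scores of the 12 arrays on the leading principal components, with 51.2% of the variance on the horizontal axis and 24.5% on the vertical axis. Each point is an array, and the 4 groups lie apart, with the collection times on opposite sides of the horizontal zero and the treatments on opposite sides of the vertical zero.

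Depolarization was followed at 30 min by a large rise of immediate-early genes. Fos, a component of the AP-1 transcription factor, was at 11.05 ± 0.18 in depolarized cultures against 6.99 ± 0.04 in controls (mean log2 ± SD, n = 3 each), 16.7-fold higher (log2 difference 4.06, SE 0.08, adjusted p = 2.02e-14 by limma), while another Fos probe set did not pass at 30 min (0.10, adjusted p = 0.291) or at 2 h (0.05, adjusted p = 0.61). Egr2 rose by 3.58 (SE 0.27), Egr1 by 3.52 (SE 0.19) and Atf3, a stress-induced transcription factor, by 2.92 (SE 0.15). Klf6 rose by 2.79, Junb by 2.47, the muscle membrane-repair gene Trim72 by 2.41 and Zfp36, whose protein destabilizes AU-rich mRNAs, by 2.35. Arc, a regulator of synaptic AMPA receptors, rose by 2.63 (SE 0.20), the vasoactive peptide gene Adm by 2.31 and Ier3 by 2.30. Slc38a2, a sodium-coupled neutral amino acid transporter, rose by 2.28 (SE 0.07).

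The falls at 30 min were smaller. Mogs, the glucosidase that starts N-glycan trimming, fell by 1.44 (SE 0.07; 7.57 ± 0.04 against 9.01 ± 0.16), and the nucleotidyltransferase gene Tut1 fell by 1.44 (SE 0.08). C17h7orf25 fell by 1.42, Zfp157 fell by 1.40, Dnajc14 fell by 1.38 and Dnmbp fell by 1.37. Atosa fell by 1.35, Tmem100 fell by 1.32 and Spart fell by 1.32. Zmym1 fell by 1.31, Trafd1 fell by 1.28 and Zkscan1 fell by 1.28. Each of these 24 genes passed adjusted p 0.05, the weakest being Egr2 at adjusted p = 1e-07, and in each all 3 depolarized arrays lay beyond all 3 controls.

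Of the immediate-early list, 28 of 30 measured genes rose at 30 min, 0 fell and 2 did not pass, and 28 rose when adjusted over the list alone (median difference 1.43, camera adjusted p = 6.11e-31, and adjusted p = 0.0347 with an estimated correlation). Nr4a1 rose by 1.78 and Dusp1, a MAP kinase phosphatase, by 1.91. Nr4a2, a transcription factor needed by dopaminergic neurons, rose by 0.87 (SE 0.08, adjusted p = 1.13e-06). Among late activity-response genes 19 of 34 rose and 0 fell, or 20 and 0 adjusted over the list alone (median 0.28, adjusted p = 9.4e-09, and adjusted p = 0.0347 with an estimated correlation). Ppp1r15a rose by 1.51, Scg2 by 1.47, Nfil3 by 1.15 and Plk2 by 0.92. Bdnf rose by 0.33 (SE 0.06, adjusted p = 0.000945), while a dimmer Bdnf probe set did not pass (0.06, adjusted p = 0.655). Of 5 Homer1 probe sets, those with larger responses rose by 1.95 and 1.32, the brightest rose by 0.24 (adjusted p = 0.03), and the others did not pass. The call on the brightest was lost without any of 4 single arrays (adjusted p from 0.0528 to 0.112).

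Genes of sterol biosynthesis rose at 30 min in 11 of 18 measured members, with 2 falls, and the counts adjusted over the list alone were also 11 and 2 (median 0.47, adjusted p = 8.91e-09, and adjusted p = 0.094 with an estimated correlation). Idi1, which isomerizes isopentenyl diphosphate, rose by 1.65, Insig1 by 1.43, the lanosterol demethylase gene Cyp51 by 1.40 and Msmo1 by 1.29. Of MAP kinase phosphatases and feedback inhibitors, 8 of 12 rose and 2 fell, or 9 and 2 adjusted over the list alone (adjusted p = 0.000142, and adjusted p = 0.24 with an estimated correlation). Errfi1 rose by 1.36, Dusp5 by 1.15 and Spry1 by 0.97.

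Stress lists shifted upward at 30 min by the camera test. Heat shock genes and chaperones rose in 7 of 19 members, with 0 falls, and in 7 adjusted over the list alone (adjusted p = 0.00114, and adjusted p = 0.439 with an estimated correlation), led by heme oxygenase Hmox1 at 1.09, Dnajb1 at 0.64 and Dnaja1 at 0.55. Another Dnaja1 probe set of similar level did not pass (0.02, adjusted p = 0.867). Of the unfolded protein and ATF4 response, 8 of 26 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.0281, and adjusted p = 0.6 with an estimated correlation). Ddit3 rose by 1.48, Dnajb9 by 0.84 and Herpud1 by 0.82, whereas Xbp1, a transcription factor of this response, fell by 0.82.

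Circadian clock genes rose in 6 of 15 members and fell in 1, with the same counts adjusted over the list alone (adjusted p = 0.0381, and adjusted p = 0.417 with an estimated correlation). Bhlhe40 rose by 1.32 and Nr1d2 by 0.59, while Dbp fell by 0.67. That list's call was lost without control replicate 2 (adjusted p = 0.0526) and without depolarized replicate 3 (adjusted p = 0.0517). Neuropeptides and granins rose in 2 of 22 members, Scg2 and Vgf (0.74), both also in the late activity-response list, with 2 adjusted over the list alone (adjusted p = 0.0479, and adjusted p = 0.24 with an estimated correlation). This call was lost without control replicate 2 (adjusted p = 0.103), depolarized replicate 1 (adjusted p = 0.0516) or depolarized replicate 2 (adjusted p = 0.0805).

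The dopaminergic marker list shifted upward at 30 min, with 3 of 23 members risen, 3 adjusted over the list alone and 0 fallen (adjusted p = 0.0285, and adjusted p = 0.581 with an estimated correlation). These were Nr4a2, at 0.87 the largest and also a member of the immediate-early list, Gch1 and Foxa2. Gch1, which makes the tyrosine hydroxylase cofactor, rose by 0.30 (adjusted p = 0.0099), and its dimmer probe set did not pass (0.17, adjusted p = 0.0743). Foxa2 rose by 0.29 (adjusted p = 0.0134). Foxa2 did not pass without control replicate 2 (adjusted p = 0.0848) or depolarized replicate 3 (adjusted p = 0.0604). The list call was lost without control replicate 2 (adjusted p = 0.0526) and depolarized replicate 1 (adjusted p = 0.0804), and with the mean of a gene's probe sets (adjusted p = 0.0595). Tyrosine hydroxylase, Th, differed by 0.19 (adjusted p = 0.369) and the vesicular transporter Slc18a2 by 0.20 (adjusted p = 0.182). The dopamine transporter Slc6a3 differed by 0.34 (adjusted p = 0.0695) and Ddc by 0.32 (adjusted p = 0.0607). Slc6a3 and Ddc passed after median centring (adjusted p = 0.037 and 0.0234), quantile normalization (0.0471 and 0.0268) and removal of the intensity trend (0.0378 and 0.0311). Their dimmer probe sets did not pass in the fit without further scaling (Slc6a3 0.05, adjusted p = 0.81, and Ddc 0.05, adjusted p = 0.816).

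The other 21 lists did not shift at 30 min by camera, though 2 of them passed with the replicate number as a block. Fry called calcium pumps, calmodulin and kinases (adjusted p = 0.0071), glycolysis and hypoxia genes (0.00922), progenitor markers (0.012) and Notch and proneural factors (0.014) upward. It called the oligodendrocyte lineage (adjusted p = 0.012) and apoptosis and p53 targets (0.0269) downward. Camera adjusted p-values follow. Pan-neuronal markers had a median of 0.12 (adjusted p = 0.0572), with the neurofilament gene Nefm risen by 0.65. That list passed with the mean of a gene's probe sets (adjusted p = 0.0281) and without control replicate 1 (0.0368), control replicate 3 (0.0117) or depolarized replicate 2 (0.0231). Notch and proneural factors (adjusted p = 0.0617) included Id1 at 1.12 and Hes1 at 1.07, which rose, and Hes6, which fell by 0.48, and passed without control replicate 3 (adjusted p = 0.0461), depolarized replicate 2 (0.0415) or depolarized replicate 3 (0.0255). Adjusted p was 0.0969 for calcium pumps, calmodulin and kinases, 0.209 for microglia, and 0.221 both for glutamate and GABA receptors and for glycolysis and hypoxia genes. It was 0.279 for the cell cycle, where 0 of 29 rose and 6 fell, with the same counts adjusted over the list alone, Ccne2 falling by 0.51. It was 0.287 for ribosomal proteins, 0.379 for apoptosis and p53 targets, for serotonergic and for progenitor markers, and 0.476 for the oligodendrocyte lineage, in which Pdgfra fell by 0.58. It was 0.502 for GABAergic markers, 0.555 for the Sonic hedgehog pathway, 0.579 for endothelium, mural cells and fibroblasts, and 0.689 for astrocytes, whose marker Gfap differed by 0.04. Voltage-gated channels were at 0.704, neurotrophic factors and the synaptic vesicle list both at 0.741, oxidative phosphorylation at 0.795 and glutamatergic markers at 0.988.

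In all, 3805 of 15866 probe sets (24%) changed at 30 min by limma's test, 1720 higher and 2085 lower, which is 1246 genes with higher and 1663 with lower expression. After median centring the split turned to 2339 higher and 1631 lower, so which direction held more calls depended on the scaling. Differences of at least 2-fold were 121 higher and 43 lower, and the ordinary equal-variance test called 2101. In 5846 probe sets (36.8%) the 3 depolarized arrays lay wholly apart from the 3 controls, where chance gives 10%. No list that shifted changed sign in its median under median centring, quantile normalization or removal of the intensity trend.

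**Figure D2:**
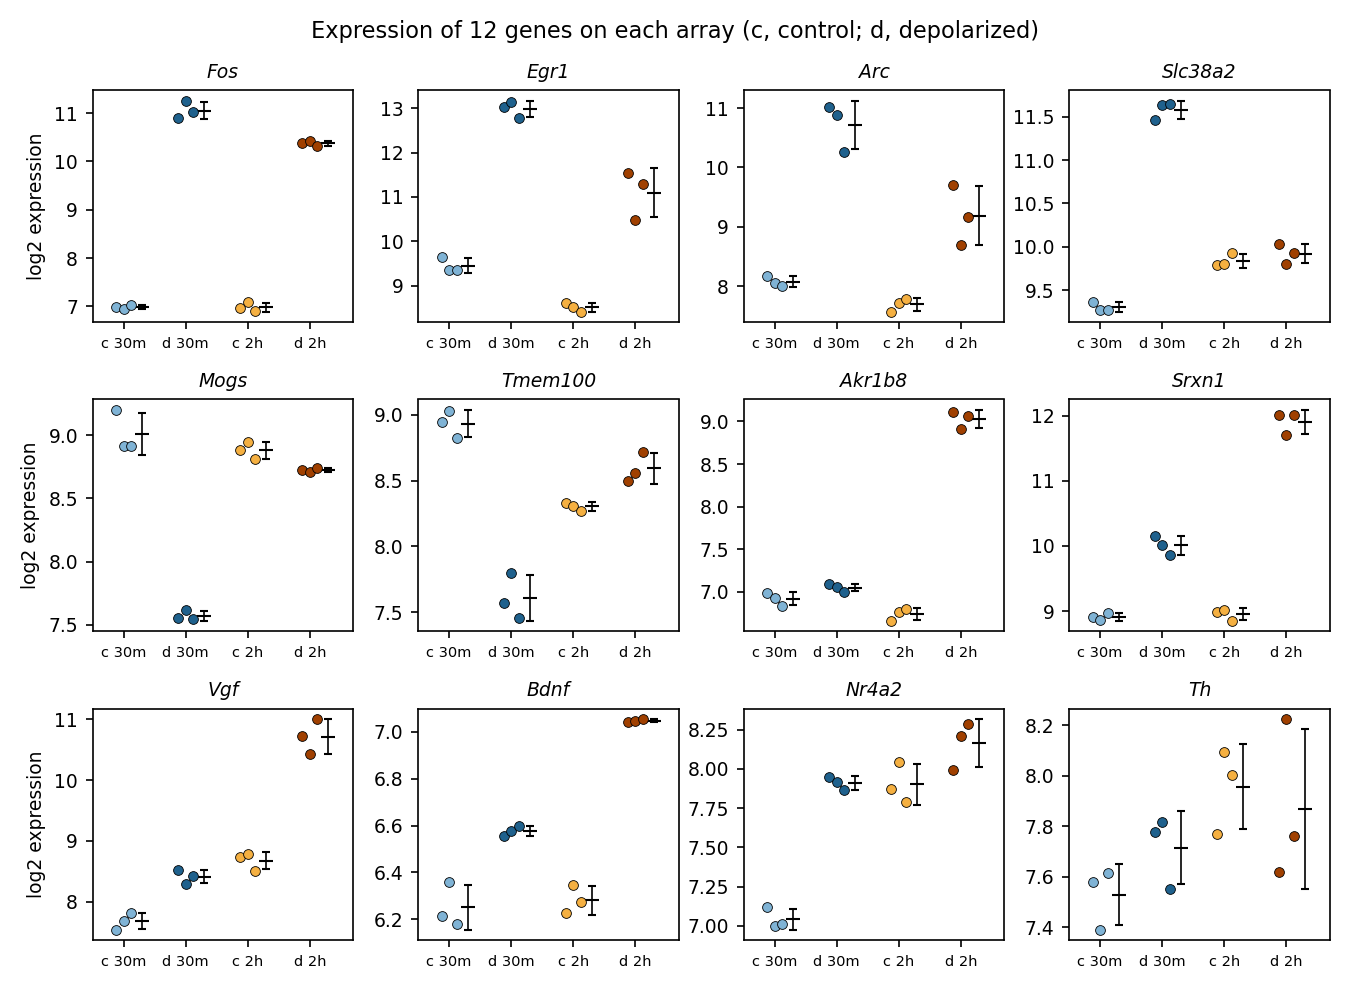
Log2 expression of 12 named genes, with a point for each array and a bar for the mean ± SD of the 3 arrays of each group (c, control; d, depolarized; 30m and 2h, collection times). Vertical axes differ between panels and do not start at 0; Fos rose at both times, Slc38a2 and Mogs differed at 30 min and not at 2 h, and Akr1b8 rose at 2 h.

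By 2 h after depolarization Fos was still 10.5-fold higher (10.37 ± 0.05 against 6.98 ± 0.09, n = 3 each; log2 difference 3.39, SE 0.08, adjusted p = 3.32e-13 by limma). Tnfrsf12a, the receptor of the cytokine TWEAK, rose by 3.16 (SE 0.16) and Fosb by 3.14 (SE 0.12). The antioxidant gene Srxn1 rose by 2.95 (SE 0.09) and the aldo-keto reductase gene Akr1b8 by 2.29 (SE 0.07). Nab2, a corepressor of EGR proteins, rose by 2.61, Egr1 by 2.59, the galectin gene Lgals3 by 2.27 and Egr2 by 2.24. Homer1, a postsynaptic scaffold gene, rose by 2.20 at the probe set with the lowest p, the linker histone gene H1f2 by 2.14 and the matricellular gene Ccn2 by 2.08. The brightest Homer1 probe set rose by 0.26 (adjusted p = 0.0173) and lost its call without depolarized replicate 4 (adjusted p = 0.0972) or 6 (adjusted p = 0.0642).

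The largest falls at 2 h were of the connexin gene Gjb2, which fell by 1.30 (SE 0.15), Ipp, which fell by 1.18, and Ankrd44, which fell by 1.04. Svil fell 2-fold and the neuronal sodium channel gene Scn2a fell by 0.98 (SE 0.07; 6.28 ± 0.09 against 7.27 ± 0.11). Acss1 fell by 0.93, Prr36 fell by 0.87 and Lyrm4 fell by 0.87. A dim Svil probe set did not pass (-0.06, adjusted p = 0.596). Stk3 fell by 0.86, Dhrs3 fell by 0.85, Cep250 fell by 0.84 and Ssbp2 fell by 0.84. Of the 24 genes named from both ends of the ranking at 2 h, the weakest was Ssbp2, with adjusted p = 7.91e-05. The falls named here are against the 2 h controls. Scn2a was at 5.9, 5.8 and 5.9 in the 30 min controls, below the depolarized arrays at 2 h (6.2, 6.3 and 6.3). For Ankrd44, Prr36 and Ssbp2 the depolarized arrays at 2 h overlapped the 30 min controls. For Gjb2, Ipp, Svil, Acss1, Lyrm4, Stk3, Dhrs3 and Cep250 they lay below both control groups.

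Late activity-response genes rose at 2 h in 22 of 34 members and fell in 1, with the same counts adjusted over the list alone (median 0.29, adjusted p = 3.88e-12, and adjusted p = 0.0239 with an estimated correlation). The secreted neuropeptide precursor Vgf rose by 2.04, the neuronal pentraxin Nptx1 by 1.96, Lmna by 1.66 and Scg2 by 1.42. Bdnf rose by 0.77 (SE 0.06; 7.05 ± 0.01 against 6.28 ± 0.06, adjusted p = 7.3e-07), and its dimmer probe set did not pass (0.10, adjusted p = 0.302). Of the immediate-early list, 25 of 30 rose and 0 fell, or 27 and 0 adjusted over the list alone (median 0.81, adjusted p = 8.22e-25, and adjusted p = 0.0515 with an estimated correlation). Arc rose 2.82-fold. Klf10 rose by 1.47, Nr4a1 by 1.23 and Nr4a2 by 0.26 (adjusted p = 0.0281). The Nr4a2 call was lost without any of 4 single arrays (control replicates 4 and 6, depolarized replicates 5 and 6; adjusted p from 0.0834 to 0.121), and a dimmer Nr4a2 probe set did not pass (0.24, adjusted p = 0.191).

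The depolarized arrays at 2 h differed in the size of this response. Replicate 5 was the lowest of the 3 in 21 of the 25 risen immediate-early genes, with a list median of 0.633 over the mean control, against 1 in replicate 4 and 0.879 in replicate 6. Egr1 was at 10.47 in replicate 5 against 11.53 and 11.29 in replicates 4 and 6, Egr2 at 7.80 against 9.45 and 9.09, and Arc at 8.70 against 9.70 and 9.17. Fos (10.42 against 10.37 and 10.33) and Fosb (9.38 against 8.89 and 9.21) were not lower in it.

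MAP kinase phosphatases and feedback inhibitors rose at 2 h in 9 of 12 members, also 9 adjusted over the list alone, with 0 falls (adjusted p = 1.49e-08, and adjusted p = 0.0792 with an estimated correlation). Dusp6 rose by 1.97, Dusp5 by 1.41, Spry1 by 1.31 and Errfi1 by 1.07 over the 2 h controls. In those controls 6 of the 12 members were lower than in the 30 min controls and 1 was higher (camera adjusted p = 0.0653). Dusp6 was at 10.7, 11.2 and 11.0 in the 30 min controls and at 9.2, 9.1 and 8.9 in the 2 h controls. At 2 h the depolarized arrays of Dusp6 (11.5, 10.4 and 11.1) and Spry1 overlapped the 30 min controls. Those of Dusp5 and Errfi1 lay above them. Neuropeptides and granins rose in 5 of 22, also 5 adjusted over the list alone (adjusted p = 0.00331, and adjusted p = 0.0814 with an estimated correlation), with Gal at 0.41 and Tac1 at 0.38 beside Vgf and Scg2. Of heat shock genes and chaperones 8 of 19 rose and 2 fell, or 9 and 2 adjusted over the list alone (adjusted p = 0.00246, and adjusted p = 0.485 with an estimated correlation). Hmox1 rose by 1.89, the cochaperone Bag3 by 1.31 and the small heat shock genes Hspb8 by 0.61 and Hspb1 by 0.41.

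Clock genes rose at 2 h in 7 of 15 members and fell in 1, or 8 and 1 adjusted over the list alone (adjusted p = 0.0065, and adjusted p = 0.24 with an estimated correlation), with Bhlhe40 at 1.67, Per2 at 0.64 and Bmal1 at 0.40. The unfolded protein and ATF4 list rose in 8 of 26, also 8 adjusted over the list alone (adjusted p = 0.0113, and adjusted p = 0.58 with an estimated correlation). It was led by Cebpb at 1.63, with Chac1 at 0.73 and Atf4 at 0.46, and its call was lost without control replicate 6 (adjusted p = 0.0674). Sterol genes rose in 7 of 18 and fell in 3, or 8 and 4 adjusted over the list alone (adjusted p = 0.0285, and adjusted p = 0.581 with an estimated correlation). Cyp51 rose by 0.90 and Fdps by 0.50, while Fdft1, the squalene synthase gene, fell by 0.68. The sterol call was lost without control replicate 6 (adjusted p = 0.0674) or depolarized replicate 6 (adjusted p = 0.0593).

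Cell cycle genes and oxidative phosphorylation genes shifted downward at 2 h. Of 29 cell cycle genes 2 rose and 12 fell, or 2 and 15 adjusted over the list alone (median -0.20, adjusted p = 0.0142, and adjusted p = 0.754 with an estimated correlation). Kif20a fell by 0.51, Plk1 fell by 0.36 and Aurkb fell by 0.33, while the cyclin gene Ccnd2 rose by 0.58, and the call was lost without depolarized replicate 5 (adjusted p = 0.17). Of 36 oxidative phosphorylation genes 0 rose and 6 fell, also 6 adjusted over the list alone (median -0.11, adjusted p = 0.0453, and adjusted p = 0.703 with an estimated correlation). Complex I gene Ndufs1 fell by 0.49 and Ndufv2 fell by 0.30. That call was lost without control replicate 4 (adjusted p = 0.116) or 5 (adjusted p = 0.0799), without depolarized replicate 5 (adjusted p = 0.0646) or 6 (adjusted p = 0.0701), and without the dimmest 25% of probe sets (adjusted p = 0.124). The actin 3' minus 5' probe set difference, a sign of RNA integrity, was 0.55 ± 0.04 in the 2 h controls and 0.44 ± 0.03 in the 2 h depolarized arrays (mean log2 ± SD, n = 3 each), against 0.37 ± 0.07 and 0.38 ± 0.05 at 30 min. For GAPDH the 2 h values were close, 0.53 ± 0.10 in controls and 0.53 ± 0.06 in depolarized arrays. At 30 min they were 0.49 ± 0.05 and 0.50 ± 0.01.

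Dopaminergic markers as a list did not shift at 2 h, with 4 of 23 risen and 1 fallen, also 4 and 1 adjusted over the list alone (adjusted p = 0.287). Th differed by -0.09 (adjusted p = 0.68), Slc6a3 by -0.22 (adjusted p = 0.239) and Ddc by 0.01 (adjusted p = 0.975). Gch1 rose by 0.44 (adjusted p = 0.000763), and Slc18a2 rose by 0.31 (adjusted p = 0.0349). Their dimmer probe sets did not pass (Gch1 -0.06, adjusted p = 0.567; Slc18a2 0.00, adjusted p = 0.993). The Slc18a2 call was lost without control replicate 4 (adjusted p = 0.185) or 5 (adjusted p = 0.0752), without depolarized replicate 4 (adjusted p = 0.0625) or 5 (adjusted p = 0.164), and after quantile normalization (adjusted p = 0.0584).

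The remaining lists did not shift at 2 h by camera. Fry called some of them, the Sonic hedgehog pathway (adjusted p = 0.00778) and glycolysis and hypoxia genes (0.012) upward. It called glutamatergic markers (adjusted p = 0.00778), progenitor markers (0.0137) and calcium pumps, calmodulin and kinases (0.0183) downward. Camera adjusted p-values follow. Microglial markers were at adjusted p = 0.0505, with Cd14 risen by 0.53, glycolysis and hypoxia genes at 0.0888 with Egln3 risen by 0.59, and the Sonic hedgehog pathway at 0.0969 with Shh risen by 0.65. The microglial list passed without control replicate 6 (adjusted p = 0.0187), depolarized replicate 4 (0.0344) or depolarized replicate 6 (0.0201), and the glycolysis list without control replicate 4 (0.0439). Voltage-gated channels (adjusted p = 0.741) had 2 of 41 risen and 6 fallen, also 2 and 6 adjusted over the list alone. Glutamate and GABA receptors (adjusted p = 0.741) had 0 of 30 risen and 6 fallen, or 0 and 5 adjusted over the list alone, Gabrb2 falling by 0.74, with its dimmer probe set not passing (-0.15, adjusted p = 0.17). Calcium pumps, calmodulin and kinases (adjusted p = 0.7) had 1 of 30 risen and 8 fallen, or 4 and 9 adjusted over the list alone, Atp2b2 falling by 0.72, with its dimmer probe set not passing (-0.04, adjusted p = 0.818). Adjusted p was 0.275 for astrocytes, with Glul risen by 0.49 and Gfap at 0.15, and 0.275 for endothelium, mural cells and fibroblasts. It was 0.428 for the synaptic vesicle list, 0.476 for neurotrophic factors, 0.485 for serotonergic and 0.494 for progenitor markers, in which Hes5 fell by 0.75 while another Hes5 probe set of similar level did not pass (0.19, adjusted p = 0.0638). It was 0.542 for the oligodendrocyte lineage, with Pdgfra falling by 0.75, 0.555 for ribosomal proteins, 0.661 for GABAergic and 0.662 for glutamatergic markers. Pan-neuronal markers were at 0.726 (median -0.09), apoptosis and p53 targets at 0.741 with Cdkn1a risen by 0.80, and Notch and proneural factors at 0.988.

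At 2 h, 4001 probe sets (25.2%) changed by limma's test, 1509 higher and 2492 lower, in 1119 and 2017 genes. Median centring gave 2014 higher and 1903 lower, so the larger share of lower calls depended on the scaling. Differences of at least 2-fold were 103 higher and 3 lower, and 5950 probe sets (37.5%) did not overlap, where chance gives 10%. At adjusted p 0.01 there were 2410 calls, and the ordinary equal-variance test on the 6 arrays gave 787.

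**Figure D3:**
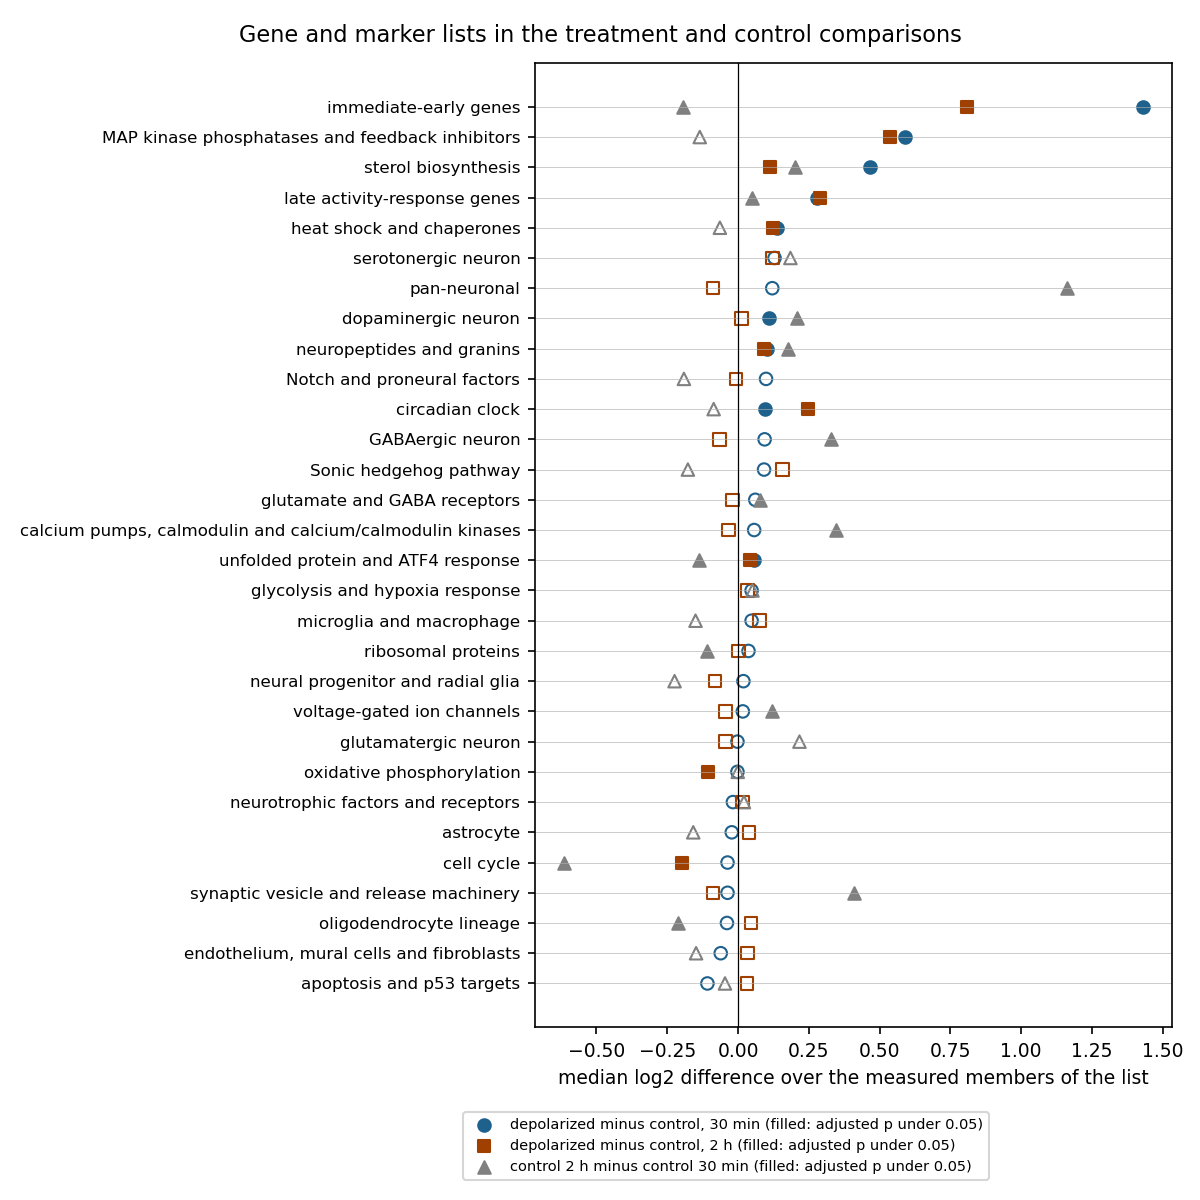
Median log2 difference (horizontal axis) over the measured members of the 30 gene and marker lists, for depolarized minus control at 30 min (circles), at 2 h (squares) and for controls at 2 h minus controls at 30 min (triangles); filled symbols had a camera adjusted p under 0.05. Immediate-early genes stood at 1.43 and 0.81 in the treatment comparisons, and pan-neuronal markers at 1.16 between the controls.

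The responses at both times were compared by overlap and by the interaction. Of the probe sets higher at 30 min, 601 were also higher at 2 h, where independent lists would share 164, and 994 were lower at both times, where 327 would be shared. Another 106 were higher at 30 min and lower at 2 h, and 112 the reverse, where independent lists would share 270 and 198. Across probe sets, which are not independent replicates, the responses correlated at r = 0.492 (rho = 0.41), with no arrays shared between them.

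The interaction named genes of early and of late response. Slc38a2 rose at 30 min and differed by 0.08 at 2 h (adjusted p = 0.481), a difference between responses of -2.19 (SE 0.11, adjusted p = 6.4e-09). The responses of Atf3 (-1.88), Klf6 (-1.61 at the probe set with the lowest p) and Dusp1 (-1.59) were also lower at 2 h. Rbbp6 rose by 1.42 at 30 min and differed by -0.18 at 2 h (interaction -1.60), while the cyclin gene Ccng2 rose by 1.06 at 30 min and fell by 0.64 at 2 h (interaction -1.70). In the other direction, the Akr1b8 response was higher at 2 h by 2.16 (SE 0.10, adjusted p = 5.29e-09), that of Srxn1 by 1.85 and that of Nptx1 by 1.63. The transporter gene Slc16a6 fell by 1.27 at 30 min and rose by 0.80 at 2 h (interaction 2.06), and Fhl2, a LIM-domain cofactor, fell by 0.48 and rose by 1.20 (interaction 1.68). Tmem100 fell by 1.32 at 30 min and rose by 0.29 at 2 h (interaction 1.61), the latter call being lost without control replicate 5 (adjusted p = 0.0579) or 6 (adjusted p = 0.0584) or depolarized replicate 6 (adjusted p = 0.0999). For Vgf the response was higher by 1.31 at 2 h (adjusted p = 9.25e-05), and for Bdnf by 0.44 (adjusted p = 0.00324).

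In total 2055 probe sets (13%) differed in response, 978 with a more positive and 1077 with a more negative response at 2 h. The split was 969 and 1190 after median centring but turned to 1156 and 1030 after quantile normalization and to 1082 and 1028 with the intensity trend removed, so it depended on the scaling. By list, the responses of sterol genes (median -0.39, adjusted p = 1.38e-06, and adjusted p = 0.591 with an estimated correlation) and of immediate-early genes (median -0.51, adjusted p = 5.77e-06, and adjusted p = 0.673 with an estimated correlation) were lower at 2 h. Of the 18 sterol genes 0 had a higher and 10 a lower response (0 and 11 adjusted over the list alone), and of the 30 immediate-early genes 2 had a higher and 14 a lower response (3 and 17 adjusted over the list alone).

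**Figure D4:**
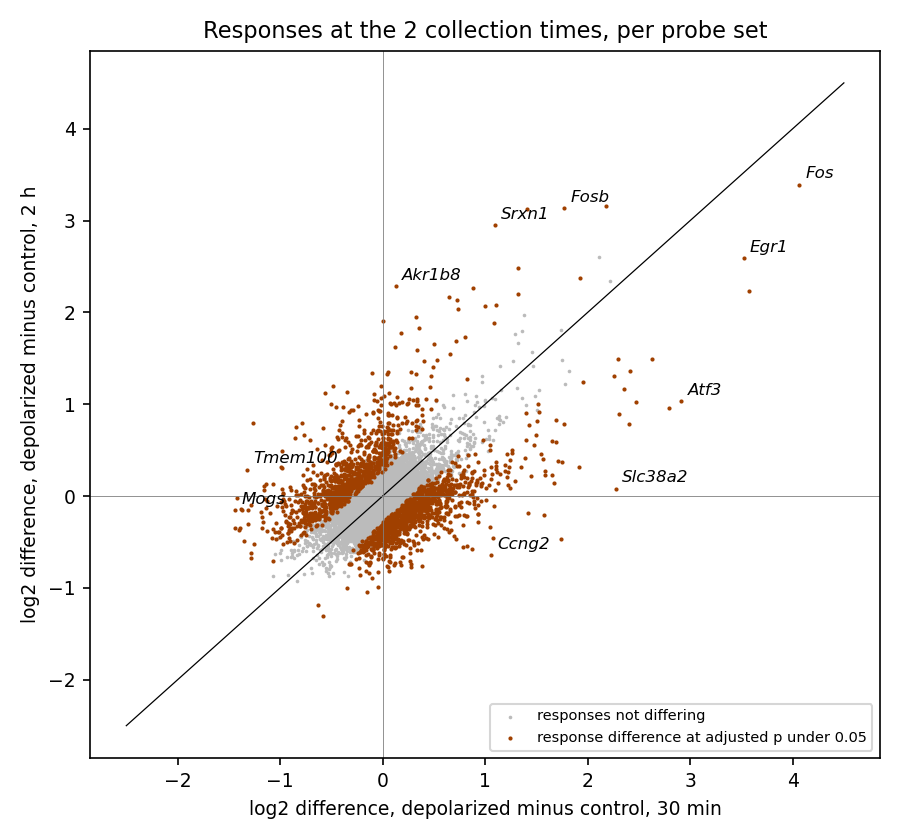
Log2 difference between depolarized and control cultures at 30 min (horizontal axis) and 2 h (vertical axis) for 15866 probe sets, with the line of equal responses. Coloured points are the 2055 probe sets whose responses differed, among them Slc38a2 (2.28 and 0.08) below the line and Akr1b8 (0.13 and 2.29) above it.

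The controls give the background against which the collection times can be set, and they differed. In the controls collected at 2 h neuronal genes were higher than in those collected at 30 min, and cell cycle and oligodendrocyte-lineage genes were lower. With an estimated correlation these list calls were lost (adjusted p = 0.0655, 0.165 and 0.0655). The retinaldehyde dehydrogenase gene Aldh1a1 was higher by 2.29 (SE 0.19; 10.36 ± 0.19 against 8.07 ± 0.18, n = 3 each), Scg2 by 2.22, C1qtnf4 by 2.10 and Spetex2l2 by 2.08. Olig1, a transcription factor of oligodendrocyte precursors, fell by 2.45 (SE 0.15; 9.78 ± 0.28 against 12.23 ± 0.27). The matrix gene Mgp fell by 1.97, Col5a3 fell by 1.83 and the smooth muscle gene Tagln fell by 1.81.

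Pan-neuronal markers were higher in 16 of 17 members, also 16 adjusted over the list alone (median 1.16, adjusted p = 1.51e-16, and adjusted p = 0.0655 with an estimated correlation), among them Mapt at 1.77 (3.41-fold) and Ina (2.84-fold). Of 29 cell cycle genes 1 was higher and 27 were lower, or 1 and 28 adjusted over the list alone (median -0.61, adjusted p = 8.52e-14, and adjusted p = 0.165 with an estimated correlation). Synaptic vesicle genes were higher in 15 of 26, also 15 adjusted over the list alone (adjusted p = 9.28e-07, and adjusted p = 0.0812 with an estimated correlation). GABAergic markers were higher in 9 of 13, or 10 adjusted over the list alone (adjusted p = 6.32e-05, and adjusted p = 0.165 with an estimated correlation). Dopaminergic markers were higher in 10 of 23 and lower in 2, or 11 and 2 adjusted over the list alone (adjusted p = 0.00107, and adjusted p = 0.26 with an estimated correlation), with Ddc at 1.47, Slc6a3 at 0.72 and Th at 0.43. Oligodendrocyte-lineage markers were lower in 7 of 12, also 7 adjusted over the list alone (adjusted p = 0.00219, and adjusted p = 0.0655 with an estimated correlation).

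Other lists that were higher in the 2 h controls were voltage-gated channels (adjusted p = 0.000427, and 0.283 with an estimated correlation), calcium pumps, calmodulin and kinases (0.000434 and 0.0655), neuropeptides and granins (0.00219 and 0.0655) and sterol genes (0.00483 and 0.283). Glutamate and GABA receptors (0.0151 and 0.26) and late activity-response genes (0.0358 and 0.26) were also higher. Ribosomal proteins (0.00576 and 0.4), immediate-early genes (0.0254 and 0.508) and the unfolded protein and ATF4 response (0.0393 and 0.46) were lower.

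Between the control groups 5604 probe sets (35.3%) differed, 2874 higher and 2730 lower at 2 h. The split turned to 2724 higher and 3140 lower after median centring and to 2593 and 2978 after quantile normalization, so which direction held more calls depended on the scaling. By camera 15 of 30 lists shifted, of which 0 did so with an estimated correlation. The 3 and 3 arrays did not overlap in 7860 probe sets (49.5%), where chance gives 10%. The difference between the depolarized groups (2 h minus 30 min), which shares no arrays with it, correlated with the control difference at r = 0.67 (rho = 0.603) across probe sets. Hybridization control transcripts added to the arrays averaged 9.98 ± 0.16 and 10.08 ± 0.06 in the 30 min groups (control and depolarized) and 9.60 ± 0.17 and 9.62 ± 0.02 in the 2 h groups.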

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

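The tests of other array splits and of the control difference, and the choice of the zinc finger genes, were made after the results were seen; the tests of the response difference and of the zinc finger genes as a class were stated before their values were seen. For the response difference, 1 of 100 splits of the arrays within each collection time, the real one, gave as many calls (2055, the highest other 1451). Regrouping arrays within a time also breaks up the treatment effect, so these splits do not test equal responses and leave open whether chance is excluded. For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The real split, 1 of the 10 in each case, gave 3805 calls at 30 min (highest other 29), 4001 at 2 h (highest other 0) and 5604 between controls (highest other 0).

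Responses that differed between the collection times, by the interaction test, stood out in 2055 probe sets. The named genes were Akr1b8 (2.16), Slc16a6 (2.06), Srxn1 (1.85), Fhl2 (1.68), Nptx1 (1.63), Tmem100 (1.61), Slc38a2 (-2.19), Atf3 (-1.88), Ccng2 (-1.70), Klf6 (-1.61), Rbbp6 (-1.60) and Dusp1 (-1.59). The immediate-early list (median -0.51, adjusted p = 0.673 with an estimated correlation) and the sterol list (median -0.39, adjusted p = 0.591 with an estimated correlation) were also among them. A different share of responding cells would scale the whole response 1 way, but of the 1988 such probe sets that changed at either time 822 had the larger response at 2 h, and the smaller side held 41.3%. A change of the controls alone would leave the depolarized groups in place. Yet in 66.9% of the 2055 the depolarized groups themselves differed in the direction of the response difference. That share has a high background, since 6507 of all 15866 probe sets differed between the depolarized groups in either direction. The response difference is computed from the depolarized and the control differences, so agreement in direction is also partly built in. The controls differed too, in 5604 probe sets. In 43.7% of the 2055 they differed opposite to the response difference, so the controls moved with a part of it. Neither share tells how much came from each side. Elapsed time after depolarization stays open as the design's own explanation, and a separate set of cultures at each time was not tested apart from it.

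Neuronal genes were higher and cell cycle genes lower in the 2 h controls than in the 30 min controls, list calls that were lost with an estimated correlation (adjusted p = 0.0655 for pan-neuronal markers and 0.165 for the cell cycle). An intensity-dependent trend as the whole cause is argued against by a pan-neuronal median of 1.13 after its removal (1.16 before), and RNA degradation in the 2 h controls by a median of 0.961 between the depolarized groups, whose actin 3' minus 5' values differed less. The GAPDH 3' minus 5' values rose little between the times, from 0.49 to 0.53 in controls and from 0.50 to 0.53 in depolarized arrays. A different cell makeup may account for it: all 10 marker lists lay on the predicted side in both the control and the depolarized difference, the 5 neuronal ones higher and the 5 others lower, though the glutamatergic, serotonergic, astrocyte, progenitor, microglial and vascular shifts did not pass the list test. These sides were set after the control results were seen, so the control difference is no test of them. The depolarized groups share the collection times, so their agreement does not separate cell makeup from other differences between the times. Hybridization control transcripts were also lower in the 2 h groups (9.60 in controls and 9.62 in depolarized arrays) than in the 30 min groups (9.98 and 10.08). A difference in array processing between the times was not tested apart from cell makeup. The neuronal lists differed in size (1.16 for pan-neuronal and 0.21 for dopaminergic markers), and a higher expression per neuron was not tested apart from a higher share of neurons. Longer time in medium cannot be told apart from separate cultures, because the depolarized groups had spent the same extra time and moved with the controls (slope 0.703 over the 5604 calls).

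Several zinc finger genes were among the largest falls at 30 min. The other 132 measured genes with such symbols were shifted downward (median -0.11, camera p = 0.000297, and p = 0.0316 with an estimated correlation), with 49 falls and 21 rises, or 39 and 23 after median centring. Low signal of their probe sets as the cause is argued against by 0% of 10000 random gene sets matched on mean level having a median as low (the lowest -0.07). At 2 h 38 of the 132 fell and 6 rose, or 30 and 8 after median centring (camera p = 0.0307, and p = 0.159 with an estimated correlation). Between the controls 40 were higher and 8 lower at 2 h (camera p = 0.00122, and p = 0.0486 with an estimated correlation). The set thus also moved outside the 30 min comparison, though the 2 h call rests on the preset correlation. A candidate explanation for the falls, loss of short-lived transcripts during or after depolarization, was not tested, since the arrays hold no half-lives.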

How the results depend on the processing

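No setting fixed before the data were seen turned the direction of a called gene or list, and of the gene results 6446 kept their side of the threshold while 308 lost it and 132 gained it; of the losses, 32 at 30 min and 82 at 2 h came from the ordinary equal-variance test. That test on the 6 arrays compared called 2101 probe sets at 30 min and 787 at 2 h, with fewer residual degrees of freedom and no shared variance prior. Stricter rules by construction gave fewer calls, with 2410 at 2 h for adjusted p 0.01, and 164 at 30 min and 106 at 2 h for at least 2-fold. With an estimated correlation camera shifted 2 lists at 30 min and 1 at 2 h, and fry, which asks another question, called 15 at each time. Neuropeptides and granins lost their call though their estimated correlation (0.00871) was below the preset 0.01. A higher correlation between members thus does not account for every loss. Of the settings chosen after seeing the data, the controls of the other collection time gave 8260 probe sets and 13 lists at 30 min, and 5845 probe sets and 18 lists at 2 h. They add the control difference to the contrast: 2769 of the 3805 calls at 30 min (72.8%) and 2052 of the 4001 at 2 h (51.3%) kept direction and threshold, 171 and 409 were called in the opposite direction, and of those at least 2-fold 162 of 164 and 96 of 106 were kept. Removing the intensity trend gave 3938, 3879, 2110 and 5465 calls at 30 min, at 2 h, for the response difference and for the controls. Leaving out each array gave 3135 to 3562 calls at 30 min, 2833 to 4070 at 2 h, 1624 to 2081 for the response difference, 4298 to 5697 for the controls, and 6 to 11 and 8 to 11 lists.

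The replicate number as a block gave 3524, 3617 and 1816 calls (30 min, 2 h, response difference) and 11 and 10 lists. The labels do not pair the numbers, and deviations of same-numbered arrays correlated at -0.322, 0.229 and 0.0513 at 30 min and 0.236, -0.107 and -0.241 at 2 h, with 4 of 12 arrays correlating best with their own number. A floor on the log scale was not run because the table is already in log2 units. With no background values in the table, how far dim probe sets lie above background is unknown; without the dimmer 50% the calls were 2817, 2943, 1598 and 3825, out of fewer tested.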

Other observations

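The sets below were chosen after the values were seen, and the genes that led to each were left out of its test; p-values are from camera, adjusted over 20 such tests. The oxidative stress genes Srxn1, Akr1b8 and Hmox1 were among the strong rises at 2 h, and all are known targets of the transcription factor NRF2. Of 18 other measured NRF2 targets 9 rose and 1 fell at 2 h (median 0.18, p = 1.54e-05, adjusted p = 4.4e-05, and p = 0.0841 with an estimated correlation). Osgin1 rose by 0.95, the glutathione synthesis genes Gclc by 0.76 and Gclm by 0.68, and Nqo1 by 0.65, while the transporter gene Abcc1 fell by 0.39. At 30 min 3 rose and 1 fell (adjusted p = 0.632): Osgin1 rose by 0.47, Sqstm1 by 0.29 and Me1 by 0.29, and Nqo1 fell by 0.26. Of the genes that led to the set, Srxn1 and Hmox1 had also risen by then, by 1.10 and 1.09. The difference between the responses gave adjusted p = 0.000396, and p = 0.13 with an estimated correlation. An NRF2 response that begins in part by 30 min and is wider at 2 h may be considered, although both calls rest on the preset correlation.

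The contractility and adhesion genes Ccn2, Fhl2, Vcl and Tes differed more from controls at 2 h than at 30 min. A Vcl probe set was at -0.45 at 30 min and 0.64 at 2 h, and Tes rose by 0.72 and 1.69. For Ccn2 this came from the controls, at 11.49, 11.71 and 11.17 at 30 min and 10.26, 10.15 and 10.08 at 2 h. Its depolarized arrays were at 12.55, 12.64 and 12.51, then 12.58, 11.87 and 12.28. Fhl2 controls lay between 8.87 and 9.10 at both times, and its depolarized arrays went from 8.52 to 8.53 at 30 min to 10.05 to 10.21 at 2 h. Of 19 other targets of SRF and its MRTF cofactors 11 rose and 0 fell at 2 h (median 0.36, p = 4.86e-08, adjusted p = 1.94e-07, and p = 0.0322 with an estimated correlation). Actn1 rose by 0.85, the zyxin gene Zyx by 0.71 and Myh9 by 0.49. At 30 min 1 rose and 2 fell (adjusted p = 0.542). The gene that rose then was Srf itself, by 0.79 and thus no less than at 2 h (0.64), while its dimmer probe set did not pass at either time. The same set was lower in the 2 h controls than in the 30 min controls, with 0 genes higher and 13 lower (median -0.33, adjusted p = 3.93e-05, and p = 0.0714 with an estimated correlation), so the rise at 2 h may partly stand for a smaller loss in depolarized cultures. Of 15 markers of endothelium, mural cells and fibroblasts, 1 was higher and 5 were lower between these controls (camera adjusted p = 0.0645). A different cell makeup was not tested apart from such a loss.

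Histone genes rose at both times while the cell cycle list did not. Several histone probe sets had led to this set, so all those at least 2-fold higher at 2 h, and any sharing a gene symbol with them, were left out of its test. Of the 10 others, 6 rose and 0 fell at 2 h (median 0.22, p = 2.45e-05, adjusted p = 5.44e-05, and p = 0.00294 with an estimated correlation), and 5 rose and 0 fell at 30 min (median 0.17, adjusted p = 0.00401, and p = 0.0175 with an estimated correlation). Among these, H3c1 rose by 0.80 at both times and H1f4 by 0.57 at 30 min and 0.67 at 2 h. Of those left out, Hist4h4 rose by 1.16 at both times and H2ac25 by 0.24 and 1.01. Some of these probe sets match several near-identical histone genes, so which copies rose is uncertain, and the 10 may still pick up transcripts of the genes left out. A change in histone transcript processing or stability may lie behind the rise, and this was not tested.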
